A study of Danio rerio with 31 samples.

How the data were processed

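Whole brains of 24 adult zebrafish were profiled by RNA sequencing in 31 runs, 1 run for 17 fish and 2 runs for 7 fish. Brains were dissected and flash frozen and RNA was extracted with the RNeasy Universal Mini kit, per the labels' protocols, and libraries were made with the TruSeq mRNA kit. Per the submitters' processing notes, the authors used bcl2fastq, cutadapt 2.1, STAR 2.7, HTSeq 0.11.2 and DESeq2 1.24.0 with the GRCz11 (danRer11) genome. The deposited values are raw HTSeq counts of reads per gene and are not normalised. The order and settings of these steps, the annotation release and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes are uncertain. The authors' differential expression results were not used here.

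Each count table held 32520 Ensembl gene IDs and the HTSeq summary lines, which name no gene and stayed out of library sizes and tests. Reads outside genes made up 16.6 to 23.5% of uniquely aligned reads, ambiguous reads 0.33 to 0.47%, and alignments that were not unique 5.98 to 28% of the reads counted with them. Symbols came from a table that named 29201 IDs and left 3319 without a symbol; the symbols often lack the zebrafish paralog suffix, and no coordinates were used. The separate gene table was of assembly GRCz12tu and served for synonyms only. Where several IDs share a symbol the paralog is not resolved, and reads of near-identical copies may have been lost or split. Among genes named below, COX5B is 1 of 3 IDs with its symbol. PRDX1, DGAT1, PDK2, GRIA3, SLC1A3, GRIN2C, KDM5B and SUZ12 are each 1 of 2. The aromatase symbol CYP19A1 matched 1 ID, and which of the aromatase paralogs it is was not resolved.

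Runs of one fish differed by a chi-square of 1.03 to 1.19 per degree of freedom over genes with at least 20 reads in all, against 18.3 to 115 for different fish of a group, and were summed. The fish is the replicate. No family, clutch or tank of the fish was used here. Differences of these between the arms or lines could therefore not be separated from the exposure or the descent, and the p-values do not cover them. Depth was 12.2 to 34.1 M gene reads per fish (median 21.5 M). A floor for a gene at 0 was set at 3 reads over the group's total, and it covers counting error only, since reads without molecular identifiers are not independent molecules. Library measures that depend on depth were taken after thinning to 12.2 M reads and compared by exact two-sided permutation tests over 21 tests.

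Genes were tested with edgeR 4.0.16 (glmQLFit with robust = TRUE, glmQLFTest) under R 4.3.3, with TMM factors, filterByExpr with its minimum count of 10, and Benjamini-Hochberg adjustment at 0.05 over all genes tested. The 12 F0 males were fitted alone; the 12 F2 fish were fitted together in 4 groups of sex and line, so that the 2 against 2 males take their spread from all F2 fish; both sexes of F2 were also fitted with sex as a term, and differences between effects were tested as interaction contrasts, over all 24 fish where they span generations. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists with at least 5 tested members. Overlaps of comparisons used Fisher's exact test on passing in both, whatever the direction, and Spearman correlations across genes. All adjusted p-values are from these tools unless another is named. DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were also used.

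The groups, the tests, the lists and the rule for named genes were fixed before the data were examined. There were 40 lists, 25 of pathways and 15 of cell types: AhR pathway, xenobiotic metabolism, oxidative stress, thyroid signalling, respiratory chain, mitochondrially encoded genes, mitochondrial dynamics, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, GABA, glutamate, dopamine and noradrenaline, serotonin, acetylcholine, stress axis, circadian clock, immediate early genes, neuropeptides, estrogen and androgen signalling, heat shock, DNA methylation and histone modifiers, ribosomal proteins, proliferation, interferon response, neurons, oligodendrocytes, radial glia, microglia, neutrophils, lymphocytes, erythrocytes, endothelium, pituitary, photoreceptors, pineal gland, muscle, epidermis, cartilage and bone, and olfactory epithelium. Of their 1238 names 1171 matched a gene ID, 910 directly, 255 without the paralog suffix and 6 through a synonym. Neutrophil markers were not tested in any comparison because fewer than 5 passed the filter, and lymphocyte and pituitary markers for the same reason not in F0 males.

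Named genes were those with an adjusted p below 0.05, at least 1 CPM in the higher arm and a symbol that is not a clone name, the 8 with the largest rise and the 8 with the largest fall per comparison, plus up to 4 members of each list with the lowest p. Where a direction had fewer than 3 calls, the 3 genes with the lowest p are given as values. Some genes that the rule picks are not reported here; they stayed in all tests and counts of genes and lists, and no other gene took their place. CYP1A1, ahrrb and CYP1B1 were always included, and in the sex contrast CYP19A1 and up to 5 genes per direction.

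The scripts were tested on simulated counts with 200 changed genes drawn from the means, spread and depth of each comparison. At 1.5-fold, 2-fold and 4-fold, 20.9, 41.8 and 78.8% of the changed genes were called in F0 males, 3, 19.4 and 43.9% in F2 females, 0, 3 and 24.2% in F2 males, 6, 35.8 and 48.5% in both sexes of F2, 0, 19.4 and 43.9% for the F0 male against F2 female effect, and 3, 28.4 and 53% for sex. All calls had the right direction, with 1 to 4 false calls per comparison, and a shifted list was called each time with 0 others. The simulated genes were drawn independently, without correlation between genes or a trend across libraries. These rates therefore do not show how often genes or lists are called wrongly in the real fish. With 200 changed genes the cutoff on the unadjusted p was also stricter than in the real F0 males, where 2060 genes passed.

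Alternatives fixed in advance were DESeq2, RLE factors, no filter on low counts, a mean of at least 1 CPM, the first run of each fish, the number of runs as a covariate, an adjusted p of 0.1, all 24 fish in one fit, only the 8 females or the 4 males, the mean of the sex contrasts, an estimated correlation or fry for lists, an unadjusted p for overlaps, and leaving out each fish. Alternatives chosen after seeing the data were limma voom with quality weights, leaving out libraries that lay apart in multidimensional scaling (F0) or had the fewest genes detected (F2), the share of reads outside genes as a covariate, and leaving out each fish for correlations. Gene length and GC content were not analysed here, because no annotation of the files' build was used.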

Results

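RNA was sequenced from the whole brains of 24 adult zebrafish of the TU line. The F0 fish were 12 males, 6 exposed to a mixture of polychlorinated biphenyls (PCBs) and polybrominated diphenyl ethers (PBDEs) and 6 controls. PCBs are chlorinated industrial oils and PBDEs are brominated flame retardants, and both persist in fatty tissue. The F2 fish had not been exposed themselves: 8 were females, 4 from the treated line and 4 from the control line, and 4 were males, 2 from each line. Gene counts summed to between 16.4 and 34.1 M reads per F0 male, 15.2 and 30.1 M per F2 female and 12.2 and 24.7 M per F2 male. The study asked what the exposure changed in the brain of exposed males and of their unexposed descendants. Expression is given in CPM, counts scaled to library size, as mean ± SD, and changes as log2 fold change of treated over control with the standard error (SE). Gene symbols are those of the name table, some of them in human form.

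In the brains of exposed F0 males, the GABA synthesis gene GAD2 and the clock gene tefa were lower than in control males, and ribosomal protein and respiratory chain genes were called higher as lists. Both of these lists lost the call with an estimated correlation (adjusted p = 0.88) and turned to lower with the share of reads outside genes as a covariate (adjusted p = 0.000245 and 6.86e-06). GAD2 (ENSDARG00000015537), which makes the inhibitory transmitter GABA from glutamate, fell from 464 ± 55.1 to 272.6 ± 48.3 CPM (n = 6 each), a log2 change of −0.77 (SE 0.113, adjusted p = 0.015). OPA1 (ENSDARG00000070801), which fuses the inner mitochondrial membrane, fell from 66.6 ± 12.3 to 39.2 ± 4.18 CPM, a log2 change of −0.77 (SE 0.12, adjusted p = 0.015). The subunit COX5B (ENSDARG00000015978) of cytochrome c oxidase rose from 410 ± 66.4 to 604 ± 130 CPM, a log2 change of 0.56 (SE 0.137, adjusted p = 0.0231), which turned to −0.02 (−0.015, SE 0.143) with that covariate. All 6 treated males lay on the stated side of the control mean for these genes. Among 18057 genes tested, 2060 passed an adjusted p of 0.05 in edgeR, 1141 higher and 919 lower in treated males. The median absolute log2 change of these genes was 0.49, and 225 of them changed by more than 2-fold.

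The largest rises among named genes included structural RNAs. The RNA of the signal recognition particle, rn7sl1 (ENSDARG00000087732), rose from 218.1 ± 52 to 484.1 ± 199 CPM, and lay above the control mean in 5 of 6 treated males (log2 change 1.15, SE 0.268, adjusted p = 0.0236). The 7SK RNA rn7sk, which holds back transcription elongation, rose by a log2 change of 1.05 (adjusted p = 0.0481) in 6 of 6. With the share of reads outside genes as a covariate the log2 change was 0.34 (SE 0.382) for rn7sl1 and −0.01 (SE 0.377) for rn7sk, and neither passed. Both RNAs lack a poly(A) tail, and the libraries were made from selected mRNA. The other rises were in sertad2a (1.05), the calcium-binding S100Z (0.99), the transcription factor ETV4 (0.98), a gene of provisional name (ENSDARG00000016213, 0.98), zhx2b (0.95) and KDELR3 (0.92), a receptor that returns proteins to the endoplasmic reticulum. With that covariate none of these passed, and their log2 changes were 0.59 for sertad2a, 0.78 for S100Z, −0.01 for ETV4, 0.87 for ENSDARG00000016213, 0.09 for zhx2b and 0.13 for KDELR3. The largest falls were in genes of low level: PIEZO1, a mechanically gated ion channel, went from 1.54 ± 0.83 to 0.191 ± 0.281 CPM (log2 change −3.01, SE 0.789, adjusted p = 0.0295). PLCB2 (−2.73), FAM161B (−2.18), pcdh1g2 (−2.13), PPTC7 (−2.02), cep135 (−2.02) and chico (−1.98) also fell. RORB, a nuclear receptor of the clock list, fell from 3.03 ± 1.21 to 0.783 ± 0.369 CPM (log2 change −1.95, SE 0.399, adjusted p = 0.0158). With the covariate none of these falls passed, and the log2 changes were −2.21 for PIEZO1, −3.14 for PLCB2, −0.27 for FAM161B, −0.61 for pcdh1g2, −1.41 for PPTC7, −1.76 for cep135, −1.24 for chico and −1.22 for RORB. Without control male 9, which stood at 6.93 CPM, PLCB2 had a log2 change of −1.88 (adjusted p = 0.155). KDELR3 and PPTC7 each share their symbol with another gene, and reads of near-identical copies could have been split between them.

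The number of genes called in F0 males depended on single fish and on a property of the libraries. Reads that aligned outside annotated genes made up 18.4 ± 1.04% of uniquely aligned reads in treated males and 20.6 ± 0.59% in controls. No value was shared between the arms, since the highest treated male had 19.5% and the lowest control 19.9% (exact two-sided permutation p = 0.00216, adjusted p = 0.0227 over 21 tests, lower than the control mean in 6 of 6). With that share as a covariate, edgeR called 0 genes, 1027 were at an unadjusted p under 0.05, and the share and the arm had a squared correlation of 0.667. Leaving out 3 libraries that lay apart from the others, treated male 16 and control males 9 and 33, left 42 genes, all among the 2060, with GAD2, tefa and NR1D2 still called. Leaving out 1 fish at a time gave 3217 genes without treated male 2, 515 without treated male 24, 1198 without treated male 36, 615 without control male 9, 748 without control male 25, 807 without control male 31 and 440 without control male 33. Of the 73 called genes of the naming rule reported here, chico, RORB, THRB, OPA1, GAD2, GAD1, GRIA3, SLC1A3, tefa, nfil3-6, NR1D2, HSPA9, KDM5B, nefma, syn2b, SOX2, ID1, cd74b and COL1A2 passed whichever single fish was left out. The other 54 lost the call without at least 1 fish: 4, 18, 14, 52, 29 and 21 of them without treated males 2, 10, 16, 24, 36 and 38, and 18, 44, 10, 42, 39 and 48 without control males 3, 9, 15, 25, 31 and 33. COX5B had an adjusted p = 0.0549 without treated male 24, 0.0541 without control male 25 and 0.0627 without control male 33.

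**Figure D1:**
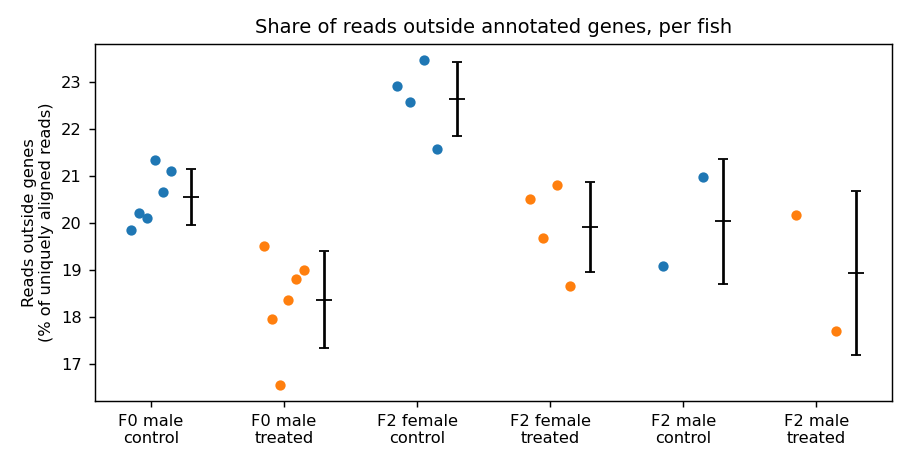
Percent of uniquely aligned reads outside annotated genes (vertical axis) in each fish (points) of the 6 groups (horizontal axis), with the group mean and SD as bars. The 6 treated F0 males averaged 18.4% against 20.6% in the 6 controls, and the 4 treated-line F2 females 19.9% against 22.6% in the 4 control-line females.

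Genes of GABA transmission were called lower as a list in exposed F0 males. Of 27 tested, 6 fell, 1 rose and 20 did not pass; adjusted over the list alone, 11 fell and 2 rose. The list was called lower as a whole (median log2 change −0.34, adjusted p = 0.00368, lower in 6 of 6 fish), but its adjusted p = 0.88 with an estimated correlation, and it ranged from 0.00278 to 0.943 over the alternatives tried. A GAD1 gene (ENSDARG00000093411) of low level fell from 5.55 ± 2.64 to 1.49 ± 0.847 CPM (log2 change −1.89, adjusted p = 0.016). The gephyrin gene GPHN, which anchors inhibitory receptors, rose by a log2 change of 0.32 (adjusted p = 0.0291). GAD1 and GPHN each share their symbol with a second gene ID. With the share of reads outside genes as a covariate the change of GAD2 was −0.42 (SE 0.148), that of GAD1 −0.715 (SE 0.623) and that of GPHN 0.03 (SE 0.104). Neither these 3 genes nor the list passed then.

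Other transmitter lists held single called genes and did not pass as lists. Of 43 glutamate genes 3 fell and 2 rose, over all genes and adjusted over the list alone (list adjusted p = 0.447). GRIA3 (−0.61, adjusted p = 0.0158) and GRIN2A (−0.43, adjusted p = 0.0229), subunits of AMPA and NMDA receptors, fell, and GRIN2C (0.47, adjusted p = 0.021) and the glial glutamate transporter SLC1A3 (0.48, adjusted p = 0.0199) rose. Monoamine oxidase mao, which degrades dopamine and serotonin, fell by a log2 change of −0.57 (adjusted p = 0.0196). It was the single call among 26 dopamine and noradrenaline genes (list adjusted p = 0.454) and among 19 serotonin genes (list adjusted p = 0.871), and it also passed adjusted over the list alone. CHAT, which makes acetylcholine, fell (−0.70, adjusted p = 0.0433), 1 of 21 cholinergic genes and 0 of 21 adjusted over the list alone (list adjusted p = 0.901). In all of these genes 6 of 6 treated males lay on the stated side of the control mean. With the share of reads outside genes as a covariate none of them passed. The log2 changes were then −0.26 for GRIA3, −0.36 for GRIN2A, 0.135 for GRIN2C, 0.52 for SLC1A3, −0.08 for mao and −0.51 for CHAT.

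Genes of protein synthesis and respiration were called higher as lists in exposed F0 males. Of 79 cytosolic ribosomal protein genes 26 rose, 0 fell and 53 did not pass; adjusted over the list alone 70 rose (median log2 change 0.41, adjusted p = 1.01e-15, higher in 5 of 6 fish). The list had an adjusted p = 0.88 with an estimated correlation, and it ranged from 1.28e-15 to 0.88 over the alternatives. RPL15 (0.57, SE 0.146, adjusted p = 0.028), RPL31 (0.48) and RPL13 (0.49) were among them. Of 91 nuclear-encoded respiratory chain genes 33 rose, 0 fell and 58 did not pass; adjusted over the list alone 75 rose (median 0.37, adjusted p = 1.39e-16, higher in 6 of 6 fish). The list had an adjusted p = 0.88 with an estimated correlation, and it ranged from 1.51e-16 to 0.88 over the alternatives. NDUFS5 (0.57), NDUFV1 (0.35) and SDHB (0.41), of complexes I and II, rose. Among 13 mitochondrially encoded genes 0 were called in edgeR, over all genes and adjusted over the list alone (list adjusted p = 0.613). With the share of reads outside genes as a covariate both lists turned to lower, with adjusted p = 0.000245 and 6.86e-06, and log2 changes turned to −0.06 (SE 0.152) for RPL15, −0.03 for RPL31, −0.07 for RPL13 and −0.05 for NDUFS5.

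Of 26 oxidative stress genes 6 rose, 1 fell and 19 did not pass; adjusted over the list alone 10 rose and 1 fell (median 0.26, adjusted p = 0.0266, higher in 5 of 6 fish). The list had an adjusted p = 0.88 with an estimated correlation and ranged from 0.011, where it turned to lower with the share covariate, to that value; it was 0.336 without the 3 libraries apart, 0.0554 without treated male 16, 0.0525 without control male 9 and 0.0898 without control male 33. The peroxidases PRDX1 (0.41, adjusted p = 0.0313), prdx5 (0.54) and GPX4 (0.44), which remove peroxides, rose, and turned to −0.05, −0.16 and −0.16 with the share covariate. Of 24 genes of mitochondrial dynamics and biogenesis 2 rose and 2 fell, also adjusted over the list alone (list adjusted p = 0.481). The fission factor mffa (0.48, adjusted p = 0.0195) and NRF1 (0.35) rose, and OPA1 and the coactivator ppargc1b (−0.44, adjusted p = 0.0489) fell. With the share covariate none of the 4 passed. The log2 change was then −0.57 (SE 0.195) for OPA1, 0.09 (SE 0.138) for mffa and 0.15 (SE 0.17) for NRF1, and ppargc1b turned to 0.15 (0.155).

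**Figure D2:**
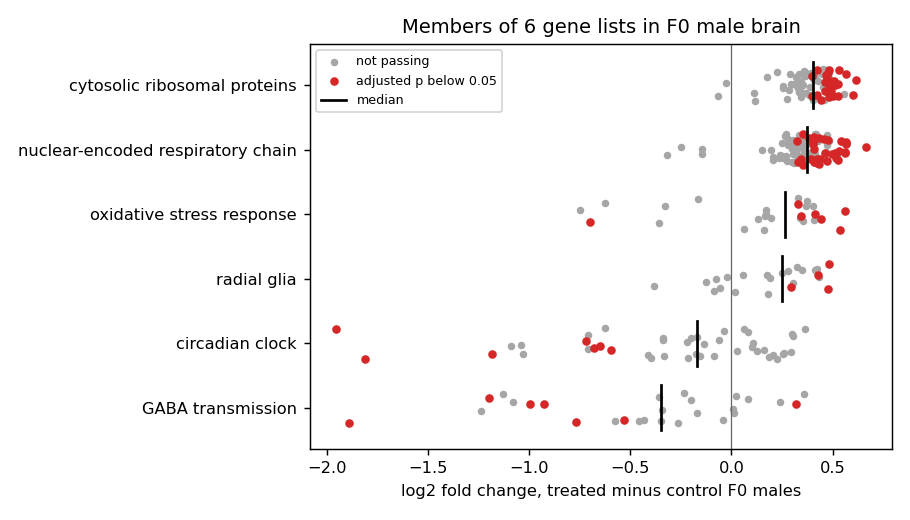
Log2 fold change of treated over control F0 males (horizontal axis) for each tested member (points) of 6 lists (vertical axis). Red points had an adjusted p below 0.05, grey points did not, and black lines are medians: 0.41 for cytosolic ribosomal proteins, 0.37 for the respiratory chain, 0.26 for oxidative stress, 0.25 for radial glia, −0.17 for the clock and −0.34 for GABA transmission.

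Clock genes that passed were lower in exposed F0 males. Of 44 tested 7 fell, 0 rose and 37 did not pass; adjusted over the list alone 8 fell and 1 rose. The list did not pass (median −0.17, adjusted p = 0.193), although its mean lay below the control mean in 6 of 6 treated males. The thyrotroph embryonic factor tefa (ENSDARG00000039117), a transcription factor of clock output, fell from 166.7 ± 20.9 to 104.4 ± 12.7 CPM (log2 change −0.68, SE 0.1, adjusted p = 0.015). The repressor nfil3-6 fell from 36 ± 12.6 to 10.3 ± 4.19 CPM (log2 change −1.81, SE 0.291, adjusted p = 0.015) and NR1D2, of the REV-ERB family, by −0.59 (adjusted p = 0.0151). With the share of reads outside genes as a covariate, the log2 change of tefa was −0.38 (SE 0.139) and of nfil3-6 −0.96 (SE 0.434), and neither passed.

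Markers of radial glia, the stem cells of the adult fish brain, were called higher as a list in exposed F0 males. Of 23 tested 4 rose, 0 fell and 19 did not pass, and adjusted over the list alone 5 rose (median 0.25, adjusted p = 0.022, higher in 6 of 6 fish). The list had an adjusted p = 0.88 with an estimated correlation and ranged from 0.0183 to 0.916 over the alternatives. SOX2 (0.48, SE 0.096, adjusted p = 0.0151), ID1 (0.43), SLC1A3 and HEPACAM (0.30) were the members that rose. The list had an adjusted p = 0.0548 without control male 33. With the share of reads outside genes as a covariate the log2 change was 0.20 (SE 0.132) for SOX2, 0.32 (SE 0.146) for ID1 and 0.17 (SE 0.136) for HEPACAM. That of SLC1A3 was 0.52 (SE 0.185), and none of these 4 passed. Of 20 neuronal markers 6 rose and 2 fell, and adjusted over the list alone 8 rose and 3 fell (list adjusted p = 0.613). The synaptic vesicle genes syn2b (0.40), sypb (0.36) and sypa (0.33) rose and the neurofilament gene nefma fell (−0.74, adjusted p = 0.015).

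Other cell markers gave few calls in F0 males. The antigen presentation gene cd74b rose (0.54, adjusted p = 0.0178), 1 of 25 microglial genes. The endothelial receptor tek rose (0.81, adjusted p = 0.0348), 1 of 23 genes and 0 adjusted over the list alone. The collagen COL1A2 rose (0.74, adjusted p = 0.0181), 1 of 26 genes of cartilage, bone and fibroblasts, S100Z was the 1 call among 7 olfactory genes, and the muscle tropomyosin TPM2 fell (−0.38, adjusted p = 0.0413), 1 of 26 muscle genes and 0 adjusted over the list alone. As lists these had adjusted p = 0.871 for microglia, endothelium, muscle and olfactory epithelium and 0.256 for cartilage. Among 18 oligodendrocyte genes 0 were called over all genes, and 2 rose and 1 fell adjusted over the list alone (list adjusted p = 0.438). Erythrocyte (10 genes, adjusted p = 0.871), pineal (6 genes, 0.304) and epidermal (17 genes, 0.653) markers held 0 calls in edgeR, also adjusted over the list alone.

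Retinal photoreceptor genes, most of which act in light-sensing cells of the eye and the pineal gland, differed more between fish of one arm than between arms. None of 38 tested passed in F0 males, over all genes or adjusted over the list alone, but the list was called higher in treated males (median 0.52, adjusted p = 0.00532, above the control mean in 6 of 6). Its adjusted p = 0.88 with an estimated correlation, and it ranged from 0.0022 to 0.912. In control males 9 and 33 the mean of 27 photoreceptor genes was 0.22 and −0.09 log2 CPM, against 3.76 to 4.38 in the other 4 controls and 3.84 to 4.34 in the treated males. Without control male 9 the list had an adjusted p = 0.0823 and without control male 33 0.0898. Without treated male 16 and those 2 controls the list turned to lower, with adjusted p = 0.912.

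**Figure D3:**
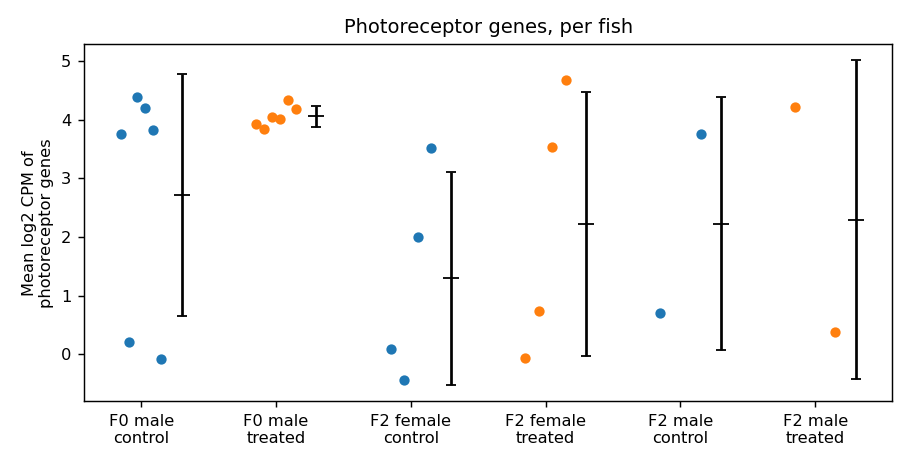
Mean log2 CPM of 27 retinal photoreceptor genes (vertical axis) in each fish (points) of the 6 groups (horizontal axis), with the group mean and SD as bars. Values lay between −0.44 in F2 control-line female 21 and 4.67 in F2 treated-line female 28.

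Hormone, lipid and stress lists did not pass in F0 males but held single calls. The thyroid hormone receptor THRB fell (−0.60, adjusted p = 0.0175) and the releasing hormone TRH rose (0.53, adjusted p = 0.0199), the 2 calls among 16 thyroid genes; adjusted over the list alone 2 rose and 1 fell (list adjusted p = 0.871). TRH was also the single call among 33 hypothalamic neuropeptides (list adjusted p = 0.193). The kinase sgk1, induced by glucocorticoids, rose (0.32, adjusted p = 0.0221), 1 of 25 stress axis genes (list adjusted p = 0.412). In lipid metabolism insig1 (−0.58), LPIN1 (−0.83), ACOX3 (−0.79) and PDK2 (−0.78) fell, and DGAT1 (0.30) and the carnitine carrier SLC25A20 (0.50) rose. These were 1 of 27 cholesterol genes, 2 of 24 genes of fatty acid synthesis and 3 of 33 of fatty acid oxidation. Adjusted over the list alone 0, 0 and 3 of them passed, and the lists had adjusted p = 0.871, 0.677 and 0.926. Estrogen and androgen signalling (15 genes, adjusted p = 0.871) and the interferon response (19 genes, adjusted p = 0.998) held 0 calls in edgeR, also adjusted over the list alone. With the share of reads outside genes as a covariate none of the genes named in this paragraph passed. The log2 changes were then −0.16 for THRB, 0.38 for TRH, 0.14 for sgk1 and −0.48 for insig1. They were −0.11 for LPIN1, −0.30 for ACOX3, −0.15 for PDK2, 0.02 for DGAT1 and 0.05 for SLC25A20.

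Of 48 heat shock and unfolded protein genes 3 rose and 1 fell, and adjusted over the list alone 7 rose and 2 fell (list adjusted p = 0.606). The mitochondrial chaperone HSPA9 fell (−0.54, adjusted p = 0.0158), while SDF2L1 (0.47), atf4a (0.54) and HSPD1 (0.29) rose. Of 48 genes for DNA methylation and histone modification 2 rose and 3 fell, and adjusted over the list alone 2 rose and 1 fell (list adjusted p = 0.677). The histone demethylase KDM5B (0.31, adjusted p = 0.0158) and the deacetylase HDAC1 (0.30) rose, and SUZ12 (−0.42) and KDM6B (−0.52) fell. Among 33 immediate early genes JUN rose (0.52) and FOSL2 fell (−0.50), also adjusted over the list alone (list adjusted p = 0.304). PCNA, the sliding clamp of DNA replication, rose (0.50, adjusted p = 0.0409), 1 of 34 proliferation genes and 0 adjusted over the list alone (list adjusted p = 0.151). With the share of reads outside genes as a covariate none of the genes of this paragraph passed, and JUN (−0.20), atf4a (−0.04), KDM6B (0.07) and PCNA (−0.06) turned. The medians or means of the thyroid, cholesterol, fatty acid oxidation, serotonin, acetylcholine, estrogen, heat shock, neuron, microglia, erythrocyte, endothelium, muscle and olfactory lists differed in sign from each other or from their tests.

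The aryl hydrocarbon receptor (AhR), the receptor of dioxin-like PCBs, switches on CYP1A1, CYP1B1 and ahrrb. CYP1A1 counted 0 to 20 reads per fish and ahrrb 0 to 3, so both were too low to be tested in F0 males. CYP1A1 stood at 0.352 ± 0.356 CPM in treated and 0.286 ± 0.257 CPM in control F0 males. In F2 control-line females it had 0 reads in 96.4 M, which allows up to 0.0311 CPM. CYP1B1 had a log2 change of −0.45 (SE 0.273, adjusted p = 0.282) in F0 males, lower in 5 of 6, and of 0.08 (adjusted p = 0.997), −0.06 (adjusted p = 1) and 0.03 (adjusted p = 0.998) in F2 females, F2 males and both sexes. Of 11 AhR genes 0 were called in F0 males, over all genes or adjusted over the list alone (adjusted p = 0.677), and likewise 0 of 24 other genes of xenobiotic metabolism (adjusted p = 0.714). CYP1B1 counted 61 to 199 reads per F0 male and was tested, so only CYP1A1 and ahrrb of these 3 were too low; in simulated F0 data 41.8% of genes changed 2-fold and 78.8% of those changed 4-fold were called.

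In F2 females no gene passed between the treated and the control line. The genes with the lowest p are given as values: fosaa, an immediate early transcription factor, stood at 8.23 ± 5.75 against 1.06 ± 0.301 CPM (n = 4 each; log2 change 2.94, SE 0.618, adjusted p = 0.424). The gonadotropin-releasing hormone gene gnrh3 stood at 21.4 ± 5.31 against 9.06 ± 2.62 CPM (log2 change 1.23, SE 0.284, adjusted p = 0.424). CYTH3 (1.59), LIN7A (−0.96), rpgrb (−2.30) and oip5-as1 (−0.76) had the same adjusted p, and all 4 fish of the treated line lay on the stated side in each. edgeR called 0 of 19463 genes, 1489 were at an unadjusted p under 0.05, DESeq2 called 34 and limma voom 0. In DESeq2 fosaa had an adjusted p = 0.00172 and gnrh3 0.0397, and over the alternatives they ranged from these values to 1.

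Among the lists, immediate early genes were called higher in treated-line F2 females (median 0.24, adjusted p = 0.00575, higher in 4 of 4), as were respiratory chain genes (0.09, adjusted p = 0.00575, 3 of 4) and photoreceptor genes (1.42, adjusted p = 0.0186, 2 of 4). All 3 had an adjusted p = 0.973 with an estimated correlation, and over the alternatives they reached from 2.93e-05, 3.63e-05 and 0.00421 to that value. No member of any list passed over all genes; adjusted over the list alone 1 of 33 immediate early genes rose and 0 of 91 and 0 of 39 of the other 2 lists. Without single fish the immediate early list had an adjusted p = 0.058 (treated-line female 6), 0.0784 (control-line female 31) and 0.268 (control-line female 39). The respiratory list had 0.17 and 0.267 without treated-line females 10 and 24, and 0.138 and 0.268 without control-line females 31 and 39. The photoreceptor list had 0.267 and 0.459 without treated-line females 24 and 28, and 0.118, 0.185 and 0.0784 without control-line females 11, 21 and 31. No list passed without control-line female 31, and 1 passed without control-line female 39. Photoreceptor genes averaged −0.06, 0.73, 3.54 and 4.67 log2 CPM in treated-line females 6, 10, 24 and 28, and 0.09, −0.44, 2.00 and 3.52 in control-line females 11, 21, 31 and 39. Lymphocyte (9 genes, adjusted p = 0.798) and pituitary (8 genes, adjusted p = 0.458) markers, too few to be tested in F0 males, held 0 calls in edgeR, also adjusted over the list alone. In the other lists, adjusted over the list alone, 1 gene of the AhR, dopamine and neuropeptide lists rose, 1 of the glutamate and acetylcholine lists fell and 2 of mitochondrial dynamics fell. Median, mean and test differed in sign in the cholesterol, fatty acid synthesis, fatty acid oxidation, glutamate, acetylcholine, chromatin, endothelium, epidermis and cartilage lists. Reads outside genes made up 19.9 ± 0.96% in treated-line and 22.6 ± 0.79% in control-line females (exact two-sided permutation p = 0.0286, adjusted p = 0.15). The lines did not overlap, since the highest treated-line female had 20.8% and the lowest control-line female 21.6%. With 4 against 4 fish this permutation p cannot go below 0.0286.

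In F2 males, with 2 fish per line, no gene passed either. GLRX, a glutaredoxin, stood at 30.8 ± 5.1 against 3.67 ± 0.41 CPM (log2 change 3.05, adjusted p = 1) and pcsk1nl at a log2 change of 0.77 (adjusted p = 1). ENTPD2, which breaks down extracellular ATP, stood at 0.248 ± 0.231 against 14.2 ± 1.85 CPM (log2 change −5.77, adjusted p = 0.274). HSPA8 (−1.14, adjusted p = 0.274) and NECAB2 (−0.92, adjusted p = 1) followed, each lower in 2 of 2 fish. A 5S_rRNA gene, one of 1947 IDs of that name, stood at 1.77 ± 1.18 CPM against 0 in both control-line males. edgeR called 0 of 19463 genes, 272 were at an unadjusted p under 0.05, DESeq2 called 6 and limma voom 4; without treated-line male 30 edgeR called 1 gene and without control-line male 25 it called 2. In simulated data of this size 24.2% of genes changed 4-fold and 3% of those changed 2-fold were found.

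In treated-line F2 males 7 lists were called, and with an estimated correlation none was (adjusted p = 0.774 for the interferon response and 0.631 for the other 6). Ribosomal protein genes were lower as a list (median −0.32, adjusted p = 4.42e-16), as were microglia (−0.47, adjusted p = 0.000845), the interferon response (−0.49, adjusted p = 0.0043) and fatty acid synthesis (−0.27, adjusted p = 0.0307). Erythrocyte markers (0.73, adjusted p = 0.00749), GABA transmission (0.24, adjusted p = 0.0253) and the clock (0.12, adjusted p = 0.0267) were called higher. Both treated-line males lay on the stated side in each list, and no member passed over all genes or adjusted over the list alone in edgeR. Over the alternatives the adjusted p of each list reached 0.95. Leaving out 1 male left the ribosomal list called each time. Without treated-line male 30 the adjusted p was 0.17 for fatty acid synthesis, 0.395 for GABA, 0.211 for the clock and for microglia and 0.161 for interferon. Without treated-line male 38, 11 lists were called and erythrocytes had 0.286. Without control-line male 25 GABA had 0.308, the clock and erythrocytes 0.258 and microglia 0.158, and without control-line male 27 fatty acid synthesis had 0.482 and interferon 0.406. In the remaining lists HSPA8, a heat shock gene, was the single gene that fell adjusted over the list alone. Median, mean and test differed in sign in the AhR, xenobiotic, fatty acid oxidation, dopamine, estrogen, endothelium, pituitary and olfactory lists. Reads outside genes made up 18.9 ± 1.74% and 20 ± 1.33% (exact two-sided permutation p = 0.667, where 2 against 2 cannot go below 0.333).

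With both sexes of F2 in a fit with sex as a term, no gene passed. The kinase SIK3 stood at 149.9 ± 23.6 against 102.3 ± 15 CPM (n = 6 each; log2 change 0.54, SE 0.108, adjusted p = 0.253). DGCR8, which processes microRNA precursors, stood at 35.5 ± 5.1 against 57 ± 13.3 CPM (log2 change −0.68, SE 0.129, adjusted p = 0.253). mgll, which degrades the endocannabinoid 2-AG, had a log2 change of −0.67 and oip5-as1 of −0.68 (adjusted p = 0.253), IRF2BP2 of 0.55 and CYTH3 of 1.31 (adjusted p = 0.311), and all 6 treated-line fish lay on the stated side in each. edgeR called 0 of 19463 genes, 1496 were at an unadjusted p under 0.05, DESeq2 called 61 and limma voom 14; edgeR called 2 without treated-line female 6 and 1 without treated-line male 30. Ribosomal protein genes (median −0.17, adjusted p = 3.62e-06, lower in 3 of 6 fish), the interferon response (−0.72, adjusted p = 0.00457, 5 of 6) and microglia (−0.24, adjusted p = 0.0204, 5 of 6) were called lower as lists and immediate early genes higher (0.14, adjusted p = 0.0204, 5 of 6). All 4 lists had an adjusted p = 0.881 with an estimated correlation, the highest over the alternatives, and the lowest were 3.37e-12, 1.3e-06, 1.5e-05 and 0.00145 in that order. Adjusted over the list alone 1 microglial gene fell and 0 members of the other 3 lists passed; elsewhere 1 AhR gene and 1 gene of mitochondrial dynamics rose, and 1 of mitochondrial dynamics and 1 cholinergic gene fell. Median, mean and test differed in sign in the fatty acid oxidation, radial glia, lymphocyte and endothelium lists. Without treated-line female 6 the adjusted p was 0.0602 for the ribosomal list, 0.101 for interferon and 0.105 for microglia and immediate early genes. The interferon list also had 0.0948 without control-line female 39. Microglia had 0.219, 0.22 and 0.065 without treated-line male 30 and control-line males 25 and 27, and 0.118 and 0.0537 without control-line females 21 and 39. Immediate early genes had 0.119 and 0.103 without treated-line females 10 and 24, and 0.126 and 0.381 without control-line females 31 and 39.

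The difference between the effects in F0 males and F2 females was called for 1 of 21082 genes, CASKIN2 (ENSDARG00000043818), a synaptic scaffold gene outside the naming rule and chosen after its values were seen, because it was the single call. Treated-line F2 females had 0 reads of it in 4 of 4 fish, against 178 reads and 1.91 ± 0.748 CPM in control-line females, so that it was at least 47.2-fold lower against the floor of 3 reads over the group. In F0 males it stood at 2.96 ± 1.35 against 6.08 ± 1.16 CPM (log2 change −0.96, adjusted p = 0.0734), and the difference had an adjusted p = 0.0157. These CPM values are without normalisation factors. edgeR called 0 genes without treated-line female 24, 6 without treated-line female 28 and 2 without treated-line female 6, treated-line female 10 or treated F0 male 2; 2456 genes were at an unadjusted p under 0.05 and DESeq2 called 68. Between F0 males and F2 males edgeR called 0 differences, 1303 genes were at an unadjusted p under 0.05, DESeq2 called 11, and 1 gene was called without F0 control male 31 or F2 control-line male 25. Between F2 females and F2 males edgeR and DESeq2 called 0, 291 genes were at an unadjusted p under 0.05, and 1 gene was called without treated-line male 30.

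Genes that differed in F0 males tended to lie on the same side in F2 females. No gene passed in both comparisons, since 0 passed in F2 females. At an unadjusted p under 0.05 in both, 521 genes moved the same way, 200 higher and 321 lower, and 41 moved in opposite ways, against 195.3 and 197.5 for independent lists of these sizes among 17868 genes. Being past that p in both comparisons, whatever the direction, had an odds ratio of 1.84 (Fisher's exact test across genes, which are not independent replicates, p = 9.43e-25); the split into same and opposite ways was not part of that test. Of the genes called in F0 males, 70% had the same sign in F2 females and 55.8% in F2 males. Between F0 males and both sexes of F2, 534 genes moved the same way and 74 in opposite ways, with 207.6 and 209.9 for independent lists (odds ratio 1.91 whatever the direction, Fisher's exact test across genes p = 3.14e-29). Between F0 males and F2 males 61 moved the same way and 26 in opposite ways, with 39.1 and 39.7 for independent lists (odds ratio 1.16 whatever the direction, Fisher's exact test across genes p = 0.278). The comparisons share no fish, but the treated fish of both F0 males and F2 females had the lower share of reads outside genes. Of 35 splits of the F2 females, the real one included, 3 gave as many as 521 genes. The absolute rho of F0 males and F2 females given next was reached by 17 of 35, so chance is not excluded for either. Across genes the changes in F0 males and F2 females had a Spearman rho of 0.12 (Pearson r 0.07), which was 0.24 without treated-line female 6, 0.20 without control-line female 21, 0.08 without treated-line female 10 and 0.05 without control-line female 31. Between F0 males and F2 males rho was −0.07, with 0.05 without treated-line male 30, −0.15 without treated-line male 38, −0.01 without control-line male 25 and −0.13 without control-line male 27. Between F2 females and F2 males rho was 0.19, with 0.12 without treated-line female 6, 0.15 without control-line female 11 or 21, 0.13 without treated-line male 38 and 0.14 without control-line male 27. There 61 genes moved the same way and 4 in opposite ways, with 10.7 and 10.1 for independent lists (Fisher's exact test across genes, whatever the direction, p = 6.51e-17). Both of these contrasts came from the same fit and shared each gene's estimate of spread. A gene of small spread can therefore pass in both without a shared effect, so that test cannot decide on one. The split into same and opposite ways was not part of it, and no splits of the fish were run for this pair.

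F2 females and F2 males differed in 3 of 19463 genes, all lower in females. DIO2 (ENSDARG00000094857), the deiodinase that makes active thyroid hormone, stood at 45.5 ± 12.1 CPM in 8 females and 183.7 ± 32.2 CPM in 4 males (4.01-fold lower, SE 0.17 on the log2 scale, adjusted p = 2.1e-05, lower in 8 of 8). ITPRID2 stood at 100.6 ± 19.6 against 163.5 ± 28.9 CPM (log2 change −0.70, SE 0.111, adjusted p = 0.036, lower in 8 of 8), with a range of 9.29e-05 to 0.479 over the alternatives. Its adjusted p was 0.0622 and 0.0884 without treated-line females 10 and 24, 0.11, 0.0736, 0.0895 and 0.116 without control-line females 11, 21, 31 and 39, and 0.479, 0.35 and 0.264 without treated-line male 38 and control-line males 25 and 27. A gene with only a clone name, si:dkey-238o13.4 (ENSDARG00000078847), outside the naming rule and chosen after its values were seen, stood at 83.5 ± 18.1 against 222.5 ± 16.9 CPM (log2 change −1.40, SE 0.146, adjusted p = 0.000138). CYP19A1, an aromatase symbol whose paralog the name table does not resolve, stood at 1.3 ± 0.913 against 0.858 ± 0.623 CPM (adjusted p = 0.999). At an unadjusted p under 0.05 there were 1006 genes, and DESeq2 called 34.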

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

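The tests of photoreceptor and clock genes, the fits without libraries that lay apart, the fit with the share of reads outside genes and the limma voom fits were chosen only after the result was seen.

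Ribosomal protein and respiratory chain genes, and most other genes called in F0 males, moved with the share of reads outside genes, which was lower in treated fish by −2.18 percentage points in F0 males and −2.72 in F2 females. Within arms, the slope of the 170 members of both lists on that share, times the difference between arms, gave a median log2 change of 0.50 (0.28 to 0.56 leaving out single fish), against 0.37 observed, and across the other 2001 genes called the change and the slope had a rho of −0.83 (−0.85 to −0.71). Treated male 16 alone did not carry the rise of both lists, since their median was 0.28 (0.275) without it. A shift in library make-up, such as RNA quality or the share of unspliced RNA, may therefore account for these calls, and the exposure could itself have shifted both; share and arm overlap too closely (squared correlation 0.667) for a covariate to part them. With it the median absolute change of the called genes went from 0.49 (median SE 0.126) to 0.15 (median SE 0.175), so the calls ended because the changes shrank as well as because the error grew.

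Genes at an unadjusted p under 0.05 in both F0 males and F2 females moved the same way in 92.7% of 562 cases. Taking the trend with the share of reads outside genes off left 82.2% (77.2 to 85.8), and as this trend was estimated from the same fish in which it goes with the line, a shared library effect and an inherited one cannot be told apart. Differences of family, clutch or tank between the arms or lines were not tested. Leaving out the 3 F2 female libraries with few genes detected gave 96.9%, which argues against those libraries as the source. Of the 35 splits of the F2 females 3 gave as many as the 521 genes, with 715 as the highest other, so chance is not excluded; for both sexes of F2 it was 4 of 100 splits for 534 genes, with 740 as the highest other, too close to 5 in 100 to exclude chance firmly, and splits above the real count point to a structure of the samples. The correlation of 0.123 was reached by 17 of 35 splits, with 0.343 as the highest other.

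Photoreceptor genes were apart in single fish rather than in arms. Of 5 pineal genes not on the photoreceptor list, 4 had their lowest values among the 12 F0 males in the same 2 fish, control males 9 and 33. Pineal or retinal tissue present in some brains and absent from others may explain the list's call in F0 males, as these 4 genes would need. No F2 fish entered this test, so it says nothing about the list's call in F2 females. A biological difference between the lines remains untested.

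For the number of genes called, 1 of 100 splits of the F0 males, the real one, gave 2060, with 1 as the highest other. These splits were a draw from all possible ones, so chance is unlikely for that count but not strictly excluded. At an unadjusted p under 0.05 the real split had 5349 genes, and a split with 1 call had 3982. In F2 females 35 of 35 splits and in both sexes of F2 100 of 100 gave as many as 0, which a count of 0 makes certain, so these splits say nothing about chance; the highest others were 18 and 25. For the difference between the F0 male and F2 female effects 24 of 100 splits gave as many as 1, with 273 as the highest other, so chance is not excluded, and a split with so many more calls points to a structure of the samples. Between the sexes 2 of 100 splits gave as many as 3, the real one included. The other of these gave 304, which again points to a structure of the samples, so chance is not firmly excluded for that count. For gene lists 58 of 100 splits in F0 males gave as many as 6 (highest other 12), 32 of 35 in F2 females as many as 3 (highest other 11) and 72 of 100 in both sexes of F2 as many as 4 (highest other 11), so chance is not excluded for any of these.

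The effect on CASKIN2 differed between F0 males and F2 females by a fitted log2 value of 7.46, which depends on the prior count because 1 group is at 0. Single fish stood apart from the rest of their group in 2 of 24 groups of library measures, 11 of 148 groups of list means and 18 of 176 groups of named genes, where chance gives about 1 in 20 groups. Treated F0 male 16 had 18681 genes with a read (others 20270 to 20805), 29% of reads in the top 100 genes (others 24.8 to 26.2), a clock mean of 5.06 log2 CPM (others 5.52 to 5.70) and a neuropeptide mean of 4.85 (others 4.38 to 4.55). It also stood at 340.5 CPM for prdx5, 851 for COX5B, 244.5 for NDUFS5, 183.2 for mffa, 262.2 for sgk1, 144.8 for JUN and 212.8 for atf4a, above the other 5, and at 137.6 for NR1D2 and 29.2 for SUZ12, below them. Treated F0 male 10 was high for PIEZO1 (0.752) and PLCB2 (1.04), and treated F0 male 2 for OPA1 (47.5). Among F0 controls male 9 was high for PLCB2 (6.93) and low for SLC1A3 (16.8), male 31 high for insig1 (159.8), male 33 high for CHAT (32.5), and male 15 high for ribosomal proteins (mean 8.79), RPL31 (534.7) and RPL13 (650.01). Thyroid genes were low in F2 treated-line female 24 (4.51, others 4.73 to 4.77) and control-line female 11 (4.51, others 4.76 to 4.80). Control-line female 21 was low for mitochondrial dynamics (4.67), serotonin (2.38), heat shock (4.83) and epidermal genes (1.97), and treated-line female 6 for heat shock (4.81) and ribosomal protein genes (8.61).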

How the results depend on the processing

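Results chosen only after seeing the data are those of limma voom, of leaving out libraries that lay apart or had few genes, of the share of reads outside genes and of single fish left out for correlations. Why a result moved was not tested here, apart from the share of reads outside genes and treated male 16 as weighed above. No paired analysis was possible because treated and control fish of one generation and sex share no fish number. In F0 males 2060 genes became 3347 in DESeq2, 3746 at an adjusted p under 0.1, 787 with all 24 fish in one fit, 42 without treated male 16 and control males 9 and 33, 0 with the share of reads outside genes (edgeR, 1027 at an unadjusted p under 0.05) and 440 to 3217 without single fish. In F2 females 0 became 34 in DESeq2, 3 with no filter, 3 with all 24 fish and 1 without treated-line females 6 and 24 and control-line female 21. In F2 males 0 became 6 in DESeq2, 3 with no filter, 1 with runs as a covariate, 22 with the 4 males alone, 4 in limma voom and 0 to 2 without single fish. In both sexes of F2 0 became 61 in DESeq2, 5 with no filter, 1 with all 24 fish, 14 in limma voom and 0 to 2 without single fish. For the F0 male against F2 female effect 1 became 68 in DESeq2, 0 without those 3 females and 0 to 6 without single fish; for the F0 male against F2 male effect 0 became 11 in DESeq2 and 0 to 1 without single fish; for F2 females against F2 males effects 0 became 1 with no filter and 0 to 1 without single fish. The 3 sex genes became 34 in DESeq2, 6 with no filter, 1 without the 3 females and 2 to 4 without single fish.

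Lists called went from 6 to 10 with the share of reads outside genes, 0 with an estimated correlation, 1 with fry and 3 to 7 without single fish in F0 males; from 3 to 10, 0, 0 and 0 to 4 in F2 females; in F2 males from 7 to 0, 0 and 5 to 11 for the last 3 settings; and in both sexes of F2 from 4 to 8, 0 and 0 with the first 3, 1 without the 3 females and 3 to 6 without single fish. Genes moving the same way in F0 and F2 went from 0 at the adjusted p to 521 in F2 females and 534 in both sexes at an unadjusted p, and to 912 and 694 without the 3 females. The correlation of F0 males and F2 females was 0.30 without the 3 females and 0.05 to 0.24 without single fish, that of F0 males and F2 males −0.15 to 0.05, changing sign to 0.053 without treated-line male 30, and that of F2 females and F2 males 0.26 at a mean of at least 1 CPM and 0.12 (0.115) to 0.22 without single fish.

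With the share of reads outside genes as a covariate, log2 changes turned to −0.012 for rn7sk, −0.007 for ETV4, −0.046 for PRDX1, −0.158 for prdx5, −0.157 for GPX4, −0.015 for COX5B, −0.046 for NDUFS5, 0.155 for ppargc1b, −0.196 for JUN, −0.037 for atf4a, 0.073 for KDM6B, −0.057 for RPL15, −0.031 for RPL31, −0.073 for RPL13 and −0.061 for PCNA. Of the 74 genes named in F0 males 58 others no longer passed, and CYP1B1 passed neither way. Some of the 58 kept much of their log2 change: SLC1A3 went from 0.479 to 0.518, GRIN2A from −0.428 to −0.361, insig1 from −0.581 to −0.481 and OPA1 from −0.768 to −0.574. Others shrank more, as mao from −0.569 to −0.078, and the median absolute change of all called genes went from 0.49 to 0.15. Oxidative stress (adjusted p = 0.011), respiratory chain (6.86e-06) and ribosomal protein lists (0.000245) turned to lower. Photoreceptor genes turned to lower without the 3 F0 libraries apart (adjusted p = 0.912). Of the 74, those on the same side of the threshold numbered 70 in DESeq2, 72 with RLE factors, 58 with no filter, 68 with the first run, 58 with runs as a covariate, 37 with all 24 fish, 68 in limma voom, 4 without the 3 libraries apart and 20 whichever single fish was left out, and the rest no longer passed.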

Other observations

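The tests in this part were chosen only after the result was seen.

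Clock genes that peak at dusk and at dawn should move in opposite ways if the arms had been sampled at different times of day. Dusk genes had a median log2 change of −0.68 (5 of 6 lower) and dawn genes of −0.20 (−0.195, 10 of 14 lower) in treated F0 males. Both medians were thus lower and not opposite. Their SEs of 0.238 and 0.076 were taken across genes of the same fish, which are not independent. The trend with the share of reads outside genes was not taken off. For these reasons the test cannot decide on a shift of the hour. The phases come from general knowledge of the clock and not from these data, and a biological change of the clock by the exposure was not tested.

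The genes for melatonin synthesis stood with the photoreceptor genes. ASMT was at 1.19 and 0.718 CPM in F0 control males 9 and 33 and at 26.2 to 65 in the other 10 F0 males, and aanat2 at 0.75 and 0.607 against 4.13 to 10.3. Both belong to the pineal list tested above, so they are no separate support.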
